A study of Mus musculus with 4 samples.

How the data were processed

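RNA-seq was measured in 4 libraries of mouse CD4+ T cells, 1 library for each combination of retrovirus (Tox2 with GFP, or GFP only) and culture (Th0 or Tfh-like). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made and sequenced at BGI. The deposited files list, for each library, whole-number read counts per gene that the authors did not normalize, per the file headers and the values. They also list FPKM, which per the file headers the authors computed for the same genes. The submitters' processing notes name Trim Galore 0.4.4, Bowtie2, featureCounts, Subread, edgeR and MACS2 and the mouse build mm10, with no role or order. Which tool made which column, the gene annotation and the strand setting are not given in the sources used here. Genes with near-identical copies or overlapping neighbours can therefore share or lose reads (Ly6 genes, Bcl2a1b and Bcl2a1d, Klrc1 and Klrc2, Stfa3, Ceacam1 and Ceacam2, Gbp and H2 genes), and their values are uncertain.

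The files hold a list of genes that had already been reduced: every gene listed had a plain CPM of at least 0.658 in its second-highest library, and the lowest sum of counts over the 4 libraries was 24. A gene silent in all groups, or above that level in only 1 library, was therefore not in the tables. Total counts were 13015283 in Th0 with GFP, 13518274 in Tfh-like with GFP, 13562334 in Tfh-like with Tox2 and 13673774 in Th0 with Tox2. At these totals a count of 0 allows up to 3 counts, or 0.216 to 0.230 CPM. The files held 0 columns of other samples.

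Counts were scaled by TMM (edgeR 4.0.16 in R 4.3.3); the factors were 1.03, 0.966, 0.987 and 1.02 in the order above. The deposited FPKM divided by the count was 1 factor per library times 1 factor per gene, with a spread of at most 5.32e-06 percent. FPKM was used only to read the authors' library scaling from it: relative to Th0 with GFP this was 0.958, 0.977 and 1.01, where TMM gave 0.971, 0.996 and 1.03 and the sum of the listed counts 1.04, 1.04 and 1.05.

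The 10960 genes with a CPM of at least 1 in at least 1 library were compared. Each of 4 pairs of libraries (Tox2 against GFP in Th0 and in Tfh-like, Tfh-like against Th0 with GFP and with Tox2) was described by the log2 fold of TMM-scaled CPM with a prior count of 2. Each fold has an exact 95% conditional binomial interval, which covers counting error only, since reads without molecular identifiers are not independent molecules. A gene was called 2-fold apart when its log2 fold was at least 1 in size and the interval excluded no difference. With 1 library per group these differences have no replicate check and no p-value is given for them; they compare libraries, not conditions.

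The 4 libraries form a layout of 2 viruses by 2 cultures, so an additive model (culture plus virus) was fitted to all of them with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom, the difference of the Tox2 effect between the cultures. That difference, moderated across genes (median prior degrees of freedom 5.52, common biological coefficient of variation 0.105), is the only measure of spread. A gene passes where its effect was large against this moderated spread, which rests mostly on other genes. Passing therefore does not require like folds in both cultures. Trhr2, for example, passed for Tox2 (log2 fold 2.77, SE 0.59) although its folds differed widely between the cultures. No p-value here measures the spread between replicates of a group, nor between animals. "Rose" and "fell" are used only of genes that passed this test. The difference of the Tox2 folds between the cultures leaves no degree of freedom and was described with a counting interval (delta method).

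Before the data were examined, 31 gene lists were fixed, together with the comparisons, their alternatives and the rule for the genes named. The rule takes Tox2, a set of 12 T-cell genes (Bcl6, Cxcr5, Pdcd1, Icos, Il21, Maf, Tcf7, Lef1, Prdm1, Il2ra, Socs3 and Tox), and the 10 higher and 10 lower genes with the largest smaller-of-both fold among genes 2-fold apart in both pairs at a CPM of 5 or more. To these it adds the 3 highest and 3 lowest genes of each pair and of the difference, and up to 4 members of each list per effect. Predicted genes and receptor segments were left out, and some genes that the rule or the lists take are not reported here. Other genes that are named were chosen after their values were seen, as members of a list that passed the test or as exceptions to a count. For a list, the number of members called is given with the median log2 fold and its percentile among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries. No percentile was computed for lists with fewer than 5 measured members.

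The procedure was tested on simulated counts drawn from the real means and library sizes, 2 Tox2 against 2 GFP libraries with 200 changed genes. The simulation had no culture effect and the same Tox2 change in both cultures, so the rates hold for that case only. With a biological coefficient of variation of 0.1 the additive test recovered 95% of the 2-fold changes and 100% of the 4-fold changes and called 10 of 10753 unchanged genes. The pairwise rule recovered 53% and 100% of them and called 29 unchanged genes in Th0, of which 0 passed in both cultures. With a coefficient of 0.2 the additive test recovered 50.5% of the 2-fold changes and 99% of the 4-fold changes and called 5 unchanged genes, and the pairwise rule called 273 unchanged genes, 4 of them in both cultures. The counting interval covered 95.4% of unchanged genes when counts varied by sampling alone and 57.6% at a coefficient of 0.1, so single pairs hold fewer sure differences than the intervals imply.

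The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors, scaling by total count, no filter, a CPM minimum of 5, prior counts of 0.5 and 10, an interval wholly beyond 1.5-fold, and leaving out the other factor. An alternative added after seeing the data removed the trends of each library on transcript GC content and length, taken from the longest annotated transcript. Gene positions are from the GENCODE M21 annotation of GRCm38, which is the mm10 build, and 10955 of the 10960 genes had a transcript there. Plots were drawn with matplotlib 3.10.9.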

Results

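Gene expression was measured by RNA-seq in naive CD4+ T cells from spleen and lymph nodes of C57BL/6 mice. The cells were activated and transduced in neutral conditions with a retrovirus carrying Tox2 and GFP, or with a control retrovirus carrying GFP only, and GFP-positive cells were then sorted and cultured. Tox2 is an HMG-box DNA-binding protein of the TOX family. The Th0 culture held antibodies that block IFN-gamma, IL-4 and IL-2, and the Tfh-like culture held the same antibodies and IL-6, a cytokine that signals through STAT3 and favours T follicular helper (Tfh) and Th17 programs. The study asked how Tox2 acts in Tfh differentiation. There was 1 library in each of the 4 groups, with total counts between 13015283 and 13673774. Mitochondrial transcripts took 2.45% of counts in both Th0 libraries, 1.99% in Tfh-like with GFP and 2.16% in Tfh-like with Tox2.

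Tox2 itself (chromosome 2, 163203125 to 163324170, plus strand, GRCm38) had 144 counts in Th0 with GFP, 851 in Tfh-like with GFP, 35297 in Th0 with Tox2 and 32246 in Tfh-like with Tox2, which follows the virus named for each library. The fold with the Tox2 virus was 7.87 on the log2 scale in Th0 (counting interval 7.65 to 8.14) and 5.20 in Tfh-like (5.11 to 5.31). Counts per gene do not separate viral from endogenous Tox2 transcripts. In the GFP libraries, where no Tox2 virus was used, Tox2 was higher in the Tfh-like culture by 2.59 (2.35 to 2.87). The other measured family members did not change with the virus: Tox had log2 folds of 0.00 and 0.14 and Tox4 0.20 and 0.02 in Th0 and Tfh-like.

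The first question was which genes differed with forced Tox2 expression over both cultures. Transcripts of central Tfh genes were among those that rose. Bcl6, the transcription factor that specifies Tfh cells (chromosome 16, 23965052 to 23988852, minus strand), was 2.83-fold higher in Th0 and 2.62-fold in Tfh-like (log2 fold over both 1.45, SE 0.11, edgeR quasi-likelihood adjusted p = 0.00300). Cxcr5, the receptor that guides cells into the follicle (chromosome 9, 44511787 to 44561877, minus strand), was higher by 2.13 and 1.73 on the log2 scale (1.94, SE 0.16, adjusted p = 0.00411). Tcf7, which encodes the transcription factor TCF-1, was higher by 1.12 and 1.16 (1.14, SE 0.10, adjusted p = 0.00417). Il6st, the signalling chain of the IL-6 receptor, rose by 1.40 (SE 0.11). Pdcd1, encoding PD-1, rose by 0.86 (SE 0.15, adjusted p = 0.0288), with 0.56 in Th0 and 1.17 in Tfh-like. Among the genes that fell were Il17f by -2.92 (SE 0.32), Gzmb, encoding granzyme B, by -3.13 (SE 0.47) and the chemokine Ccl20 by -3.59 (SE 0.37).

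Under the rule for named genes, the 10 genes with the largest log2 fold common to both cultures included Psd2 and Cxxc5. Their log2 folds over both cultures were 4.23 (SE 0.22) and 3.96 (SE 0.14), and Cxxc5 encodes a CXXC zinc finger protein. Susd2 was higher by 6.34 in Th0 and 3.95 in Tfh-like, the potassium channel subunit Kcnmb1 by 3.65 and 4.24, the glutamate transporter Slc1a2 by 3.42 and 5.45, and Dkk3 by 3.02 and 4.78. Slc37a2, Slc16a11, Pmp22 and the Wnt ligand Wnt10b completed the 10, with log2 folds over both cultures of 3.03, 3.13, 3.26 and 2.85. At the other end stood Foxf2 (-2.42 and -2.49), the cytokine osteopontin Spp1 (-2.45 and -2.10), the NK receptor gene Klrc1 (-2.83 and -2.07), the collagen gene Col5a3 (-2.83 and -1.97), Dgkk (-1.80 and -2.34), the transsulfuration enzyme Cth (-1.92 and -1.71) and Ramp3 (-1.69 and -1.67). All 20 of these genes passed the additive test, with adjusted p from 0.000407 for Cxxc5 to 0.0184 for Gzmb. They were chosen for large folds in both pairs of the same libraries, so passing adds no separate support. Klrc1 has a near-identical copy, so its counts are uncertain.

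**Figure D1:**
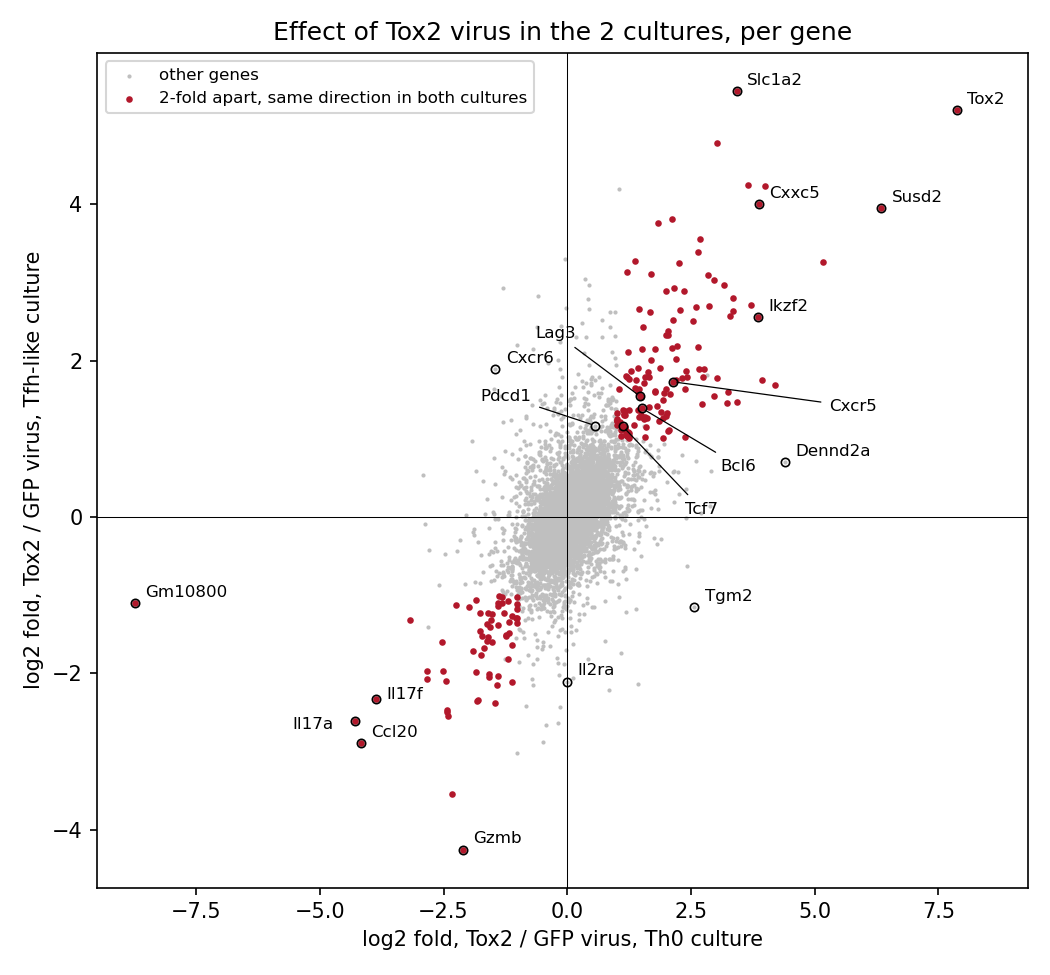
Each point is 1 of 10960 genes, placed by its log2 fold of Tox2 over GFP virus in the Th0 culture (x axis) and in the Tfh-like culture (y axis); red points are the 135 genes higher and 62 lower by at least 2-fold in both. Bcl6, Cxcr5, Tcf7 and Lag3 lie in the upper right and Il17a, Il17f, Ccl20 and Gzmb in the lower left, while Il2ra, Tgm2 and Cxcr6 lie off the diagonal.

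Over both cultures 746 of 10960 genes passed the edgeR test and 3003 had an unadjusted p under 0.05 in it. Counts in the lists are to be read against these shares. Of the 746, 446 were up and 300 down. With the GC and length trends of each library removed, an alternative chosen after seeing the data, the split was 369 up and 379 down, and DESeq2 called 484 genes. In single pairs, 519 genes were 2-fold apart in Th0 (348 higher, 171 lower) and 521 in Tfh-like (313 higher, 208 lower). Of these, 135 were higher and 62 lower in both, where independent lists would share 9.94 and 3.25. In opposite directions went 9 genes, no more than independent lists of these sizes would give. Across genes, which are not independent replicates, the folds in the 2 cultures had a Pearson r of 0.580 and a Spearman rho of 0.544. These pairs share no library, but the cells were transduced and sorted before culture, so the pairs may share that step.

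Among the 25 measured genes of the Tfh list, 5 rose and 6 fell with Tox2 (13 passed when adjusted over the list alone), and the list's median log2 fold was -0.07 in Th0 and 0.02 in Tfh-like. The 5 that rose were Bcl6, Cxcr5, Pdcd1, Tcf7 and Il6st. Cd200, a Tfh surface protein, fell by -1.16 (SE 0.11), the inhibitory receptor Btla by -0.69 (SE 0.10) and the transcription factor Irf4 by -1.09 (SE 0.13), as did Il6ra, Id3 and Angptl2. Icos, the Tfh costimulatory receptor, had log2 folds of -0.18 and -0.42 and Lef1 0.28 and 0.33, neither of which passed. Il21, the Tfh cytokine, had 1015 counts in Tfh-like with GFP and 863 with Tox2, a log2 fold of -0.27. Maf, its transcriptional activator, was lower with Tox2 in Th0 (-1.59) but not in Tfh-like (-0.14), and did not pass. Socs3, a target of STAT3, rose by 1.01 (SE 0.16). In the IL-6/STAT3 list, of 19 measured genes 4 rose and 2 fell (9 adjusted over the list alone); its medians were 0.04 in Th0 and -0.12 in Tfh-like.

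The list of inhibitory receptors and associated genes had a median above 0 with Tox2. Of 15 measured genes 7 rose and 3 fell (13 adjusted over the list alone), with medians of 0.47 in Th0 and 0.79 in Tfh-like, each above all 10000 matched random lists. Lag3 rose by 1.51 (SE 0.10, adjusted p = 0.00216), Cd160 by 1.48 (SE 0.28), Cd101 by 1.40 (SE 0.13), Tigit by 0.95, and Nr4a1 and Nr4a2 by 0.63 and 0.79. Pdcd1lg2, encoding the ligand PD-L2, fell by -1.03 (SE 0.17), and Btla and Cd274, encoding PD-L1, also fell. This list and the Tfh list share Pdcd1, Btla and Tox.

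The list of Th1 and cytotoxic genes had a median below 0 with Tox2 in both cultures. Of 20 measured genes 7 fell and 1 rose (10 adjusted over the list alone), and the medians of -0.44 in Th0 and -0.65 in Tfh-like lay below all 10000 random lists. Beside Gzmb, the chemokine receptor Cxcr3 fell by -0.97 (SE 0.17), and so did Ccl4 by -1.37 (SE 0.20), Nkg7, Fasl and Il12rb1. The T-box factor Eomes was the exception and rose, by 1.67 in Th0 and 2.62 in Tfh-like (SE of the joint estimate 0.32). Tbx21, encoding T-bet, was lower in Tfh-like (-1.39) and not in Th0 (0.08), and did not pass, nor did perforin Prf1 (0.05, SE 0.23).

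In the Th17 list 5 of 16 measured genes fell and 1 rose (7 adjusted over the list alone), with medians of -0.25 in Th0 and -0.13 in Tfh-like. Il17a (chromosome 1, 20730905 to 20734496, plus strand) had 56 counts in Th0 with GFP and 1 with Tox2, and 2125 and 355 in Tfh-like, a ratio of 6.14 (log2 fold -2.61). Il17f had 1018 and 70 counts in Th0 and 12709 and 2593 in Tfh-like. Ccl20, Irf4 and the leukotriene receptor Ltb4r1 also fell and Rora rose by 0.64. Il23r was not changed, at 657 and 661 counts in Tfh-like.

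The regulatory T-cell and Th2 lists each held members that passed in both directions. Ikzf2, encoding Helios, rose by 3.31 (SE 0.28, adjusted p = 0.00456) and Ikzf4 by 1.22 (SE 0.18), while Gpr83 and Izumo1r fell, out of 13 measured regulatory T-cell genes (7 adjusted over the list alone; medians -0.28 and -0.36). Il13 (4, 1, 19 and 61 counts in Th0 with GFP, Tfh-like with GFP, Tfh-like with Tox2 and Th0 with Tox2), Ccr8 (1.51, SE 0.12) and Gata3 (0.60) rose and Areg fell, out of 8 measured Th2 genes (5 adjusted over the list alone; medians 0.32 and -0.13). In the list of T-cell receptor activation genes 3 of 25 rose and 1 fell (13 adjusted over the list alone; medians 0.02 and 0.09); the chemokine Xcl1 rose by 2.60 (SE 0.23). In the list of genes that oppose the Tfh fate, 0 of 13 passed with edgeR, 0 adjusted over the list alone and 0 with DESeq2 or limma-voom (medians 0.26 and -0.16). An unadjusted p under 0.05 in edgeR was found for 2 of the 13, against 3003 of all 10960 genes. Proliferation genes were slightly lower, with medians of -0.33 and -0.27 over 26 genes, below all random lists; 3 fell (15 adjusted over the list alone), among them Mcm3 and Mcm5, and none was 2-fold apart in either culture.

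These values have no replicate check. With DESeq2 fewer genes passed for Tox2 in some lists: 9 and not 11 in the Tfh list, 4 and not 6 in the Th17 list, 2 and not 4 in the Th2 list, 3 and not 4 in the regulatory T-cell list, 5 and not 6 in the IL-6/STAT3 list, 2 and not 3 in the IL-2/STAT5 list and 1 and not 3 in the proliferation list. The Tox2 fold in Th0 was correlated with transcript length across genes (Spearman rho 0.331, and 0.125 in Tfh-like), and with GC and length trends removed the Th17 median in Th0 was -0.21 (percentile 3.12) and the regulatory T-cell median in Th0 was -0.12 (percentile 16.7). With a prior count of 10 the Th17 median in Th0 was -0.10, inside the range of random lists, and at a CPM of at least 5 the regulatory T-cell median in Th0 was -0.14 (percentile 9.77).

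The next question was where the effect of Tox2 differed between the cultures. Il2ra, the high-affinity IL-2 receptor chain, had a log2 fold of 0.00 with Tox2 in Th0 and -2.11 in Tfh-like (counting interval -2.17 to -2.05), so the higher Il2ra of the Tfh-like culture with GFP (12209 against 5402 counts) was not seen with Tox2 (2906 against 5591). Genes of cholesterol synthesis were lower with Tox2 in Tfh-like, with a median of -0.73 and only 1 of 19 genes above 0, against a median of 0.01 in Th0; the median difference of -0.71 lay below all random lists. So did those of the genes that oppose the Tfh fate (-0.50), naive and memory genes (-0.41), IL-2/STAT5 genes (-0.36) and glycolysis and hypoxia genes (-0.28). The list opposing the Tfh fate shares 6 genes with the naive and memory list and 2 with the IL-2/STAT5 list. In each of these lists, cholesterol synthesis included, at most 2 members had Tox2 folds 2-fold apart between the cultures. Regulatory T-cell (-0.46), chromatin (-0.25) and IL-6/STAT3 (-0.23) medians lay in the lowest 2.5% of random lists. Th17 (0.23), apoptosis (0.15), inhibitory receptor (0.14) and CD4+ T-cell (0.10) medians lay in the highest 2.5%. GC and length trends were not removed from these differences. Fdps, Mvd, Lss and Acat2 were lower by -1.21, -1.15, -1.14 and -1.03 in Tfh-like and by -0.35, -0.07, -0.07 and -0.39 in Th0. The IL-2/STAT5 list had medians of -0.23 and -0.35, with Gzmb 2-fold lower in both cultures and Socs2 in Tfh-like (-1.57); over both cultures 1 gene rose and 2 fell (10 adjusted over the list alone).

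By the counting interval, the Tox2 folds differed by at least 2-fold between the cultures in 410 genes, 195 with a higher fold in Tfh-like (119 at a CPM of at least 5) and 215 in Th0. Simulated libraries in which no Tox2 fold differed between the cultures gave 93 such genes at a coefficient of variation of 0.1 and 1122 at 0.2. The count lies between these. The fitted common coefficient of 0.105 cannot choose between the settings, since it was itself estimated from the differences of the Tox2 folds between the cultures. The simulation used 1 coefficient for all genes, so how many of the 410 exceed noise stays open. The largest were Tgm2, Dennd2a and Krt83 on the Th0 side, with differences of -3.73, -3.70 and -3.56, and Dysf, Trhr2 and Cxcr6 on the Tfh-like side. Dennd2a had 24 and 568 counts in Th0 with GFP and Tox2 and 19 and 33 in Tfh-like. Dysf had 13 and 0 counts in Th0, at least 4.48-fold lower with Tox2 against a floor of 3 counts, and 263 and 392 in Tfh-like. Trhr2 had 1 and 0 counts in Th0 and 15 and 121 in Tfh-like. Among the highest and lowest genes of single pairs, H2-Eb2 had 18 and 738 counts in Th0 (log2 fold 5.16) and 0 and 17 in Tfh-like, at least 5.53-fold. Gap43 had 237 and 19 counts and Tmem163 227 and 27 in Tfh-like with GFP and Tox2, log2 folds of -3.54 and -3.02.

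**Figure D2:**
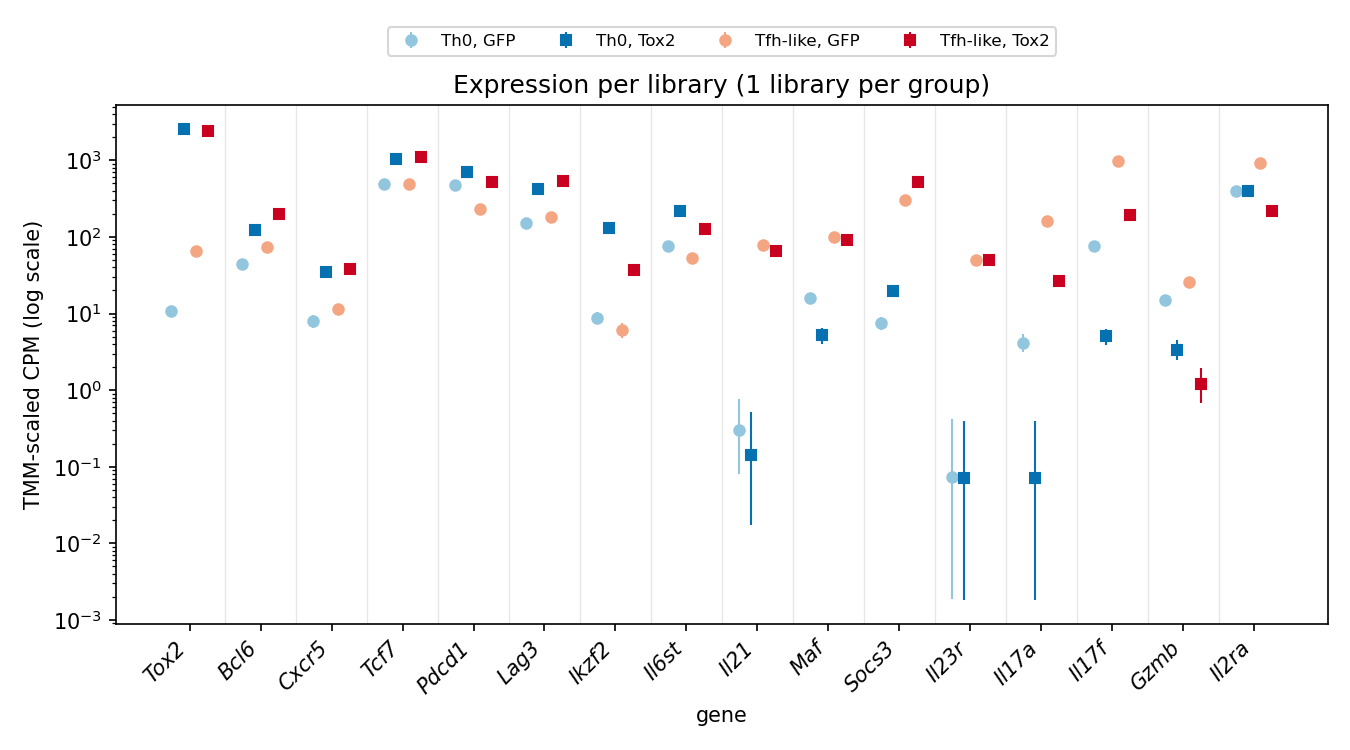
TMM-scaled CPM on a log axis for 16 genes (x axis) in each of the 4 libraries; bars are exact 95% Poisson intervals of the count, which cover counting error only. Bcl6, Cxcr5, Tcf7 and Lag3 are higher in both Tox2 libraries (squares) than in the GFP library of the same culture (circles), and Il21, Il23r and Socs3 are higher in both Tfh-like libraries (red and orange) than in both Th0 libraries (blue).

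The culture comparison asked which genes differed between the libraries with and without IL-6, with either virus. Il21 (chromosome 3, 37222759 to 37232636, minus strand) had 4 counts in Th0 and 1015 in Tfh-like with GFP, a ratio of 261 (counting interval 102 to 961), and 2 and 863 with Tox2, a ratio of 448 (124 to 3704). Il23r, the IL-23 receptor (chromosome 6, 67422932 to 67491855, minus strand), had 1 and 657 counts with GFP, a ratio of 676 whose counting interval has a lower end of 121, and 1 and 661 with Tox2. Socs3 was higher by 5.33 with GFP and 4.71 with Tox2 (log2; SE over both 0.18, edgeR adjusted p = 5.03e-05), Maf by 2.64 and 4.08 (3.28, SE 0.31) and Batf, a factor of both Tfh and Th17 cells, by 2.15 and 3.11 (2.63, SE 0.22). Bcl6 rose by 0.71 (SE 0.10, adjusted p = 0.00486), while Cxcr5 (0.53 with GFP and 0.13 with Tox2), Tcf7 (0.01 and 0.05) and Lef1 (-0.00 and 0.05) did not pass. Pdcd1 fell by -0.72 (SE 0.15) and Tox by -0.68 (SE 0.10).

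Other genes with a large increase in both viruses were Timp1, an inhibitor of metalloproteinases (log2 7.07 and 6.92), Crispld2 (10 and 1217 counts with GFP, 3 and 764 with Tox2), Ly6a, encoding Sca-1 (6.69 and 7.36), the uridine phosphorylase gene Upp1 (6 and 749 counts, 3 and 383), Cdh17 (1 and 1183 counts, 6 and 534), Il17a (56 and 2125, 1 and 355) and Ly6i (1 and 96, 1 and 134). Ly6a and Ly6i belong to a family of near-identical genes. Among genes 2-fold apart with both viruses at a CPM of 5 or more, the largest decreases were of Stfa3 (407 and 2 counts with GFP, 378 and 13 with Tox2), the cation channel Trpa1 (-4.60 and -4.35), Shisa8 (-4.12 and -3.94), Otx1 (-3.62 and -3.31), the IL-9 receptor Il9r (-3.21 and -3.65), Wnt10b (-3.17 and -3.34), the pattern receptor Nod1 (-3.80 and -3.17), Dnah7a (-3.14 and -3.33), Tal2 (-3.47 and -3.04) and the chemokine Cx3cl1 (-3.17 and -3.03). Stfa3 also has near-identical copies. All of these genes passed the test, which adds no separate support, since they were chosen for large folds with both viruses in the same libraries. Among the extremes of single pairs, Neto1 fell, with 95 and 2 counts with GFP and 111 and 18 with Tox2, and Wnt1 and Agr3 fell from 378 to 11 and from 122 to 1 counts with Tox2.

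In all, 2656 of 10960 genes passed the edgeR test and 4120 had an unadjusted p under 0.05 in it. Counts in the lists for the culture are to be read against these shares. Of the 2656, 1564 were up and 1092 down. The split depends on the scaling: with total counts alone it was 1500 up and 1649 down, where the median of all genes in the GFP pair shifted to -0.11, and with GC and length trends removed 1415 up and 1827 down; DESeq2 called 1619 genes. With GFP 1194 genes were 2-fold apart (853 higher, 341 lower) and with Tox2 1033 (719 higher, 314 lower), 549 of them higher and 170 lower in both, where independent lists would share 56.0 and 9.77. The folds of these pairs, which share no library, had a Pearson r of 0.811 across genes.

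The lists described the difference between the culture libraries in detail. Of 19 measured IL-6/STAT3 genes 17 rose and 1 fell (18 adjusted over the list alone), with medians of 1.87 with GFP and 1.26 with Tox2, above all random lists; Stat3 rose by 1.24, Bcl3 by 2.93 and Il4ra by 1.65, and Il6st fell by -0.64. Of 16 Th17 genes 13 rose and 1 fell (14 adjusted over the list alone; median 2.14 with GFP, and above all random lists with either virus), among them Ahr (2.08) and the IL-1 receptor Il1r1 (5.03, SE 0.35), while Ccr6 fell by -0.68. These lists share 7 genes. Of 20 Th1 and cytotoxic genes 10 rose and 4 fell (16 adjusted over the list alone; medians 0.72 and 0.92): Tbx21 rose by 5.40 (SE 0.32), Il12rb2 by 5.77 (SE 0.52) and perforin Prf1 by 3.62 (SE 0.25), and Eomes fell by -2.86 (SE 0.32). In the Tfh list 8 of 25 rose and 9 fell (17 adjusted over the list alone; medians -0.00 and 0.03), with Ascl2 at 2.22 and S1pr2 at 1.34 among those that rose and Btla at -1.21 and Slamf6 at -0.84 among those that fell.

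Glycolysis and hypoxia genes rose together: 17 of 24 rose (19 adjusted over the list alone; medians 0.68 and 0.40). The oxygen sensor Egln3 rose by 2.02 (SE 0.21), the glucose transporter Slc2a3 by 1.69 (SE 0.20), Vegfa by 1.58 (SE 0.14) and Aldoc by 1.25 (SE 0.20). The housekeeping list, which shares Gapdh with it, had medians of -0.04 and -0.12, with Gapdh up and Gusb down out of 13 genes (2 adjusted over the list alone); with Tox2 its medians were -0.08 and -0.16, and 0 passed with edgeR, DESeq2 or limma-voom (4 adjusted over the list alone, and 4 at an unadjusted p under 0.05). Interferon response genes were higher: 9 of 19 rose and 1 fell (14 adjusted over the list alone; medians 0.64 and 0.55), with Gbp2 at 1.87, Oas3 at 1.32 and Ddx58 at 1.15. In the IL-2/STAT5 list 9 of 17 rose (9 adjusted over the list alone; medians 0.71 and 0.50), including Socs1 (1.78) and Lif (2.06). Of the genes that oppose the Tfh fate 6 of 13 rose and 4 fell (10 adjusted over the list alone; medians 0.50 and 0.43), Id2 by 2.52 and S1pr1 by 1.22 up and Klf2 by -1.09 down. Prdm1, encoding Blimp-1, had 15, 20, 29 and 9 counts in Th0 with GFP, Tfh-like with GFP, Tfh-like with Tox2 and Th0 with Tox2, and did not pass.

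Of 25 genes induced by T-cell receptor signals 11 fell and 6 rose in the Tfh-like culture (18 adjusted over the list alone; medians -0.65 and -0.32, below all random lists). Nr4a3 fell by -2.11 (SE 0.16), Nr4a1 by -1.67 (SE 0.12), the phosphatase Dusp5 by -2.34 (SE 0.19) and Il2 by -1.34, while the AP-1 genes Jun and Fosl2 rose by 1.77 and 1.76. Of the inhibitory receptor list, which shares the 3 Nr4a genes, 7 of 15 fell and 2 rose (10 adjusted over the list alone; medians -0.75 and -0.30), with Ctla4 up by 0.97 and Cd200r1 by 1.67. Proliferation genes were lower, with 16 of 26 down (21 adjusted over the list alone; medians -0.42 and -0.40) and none 2-fold apart; Mki67 fell by -0.45 (SE 0.11) and Mcm2 by -0.73.

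**Figure D3:**
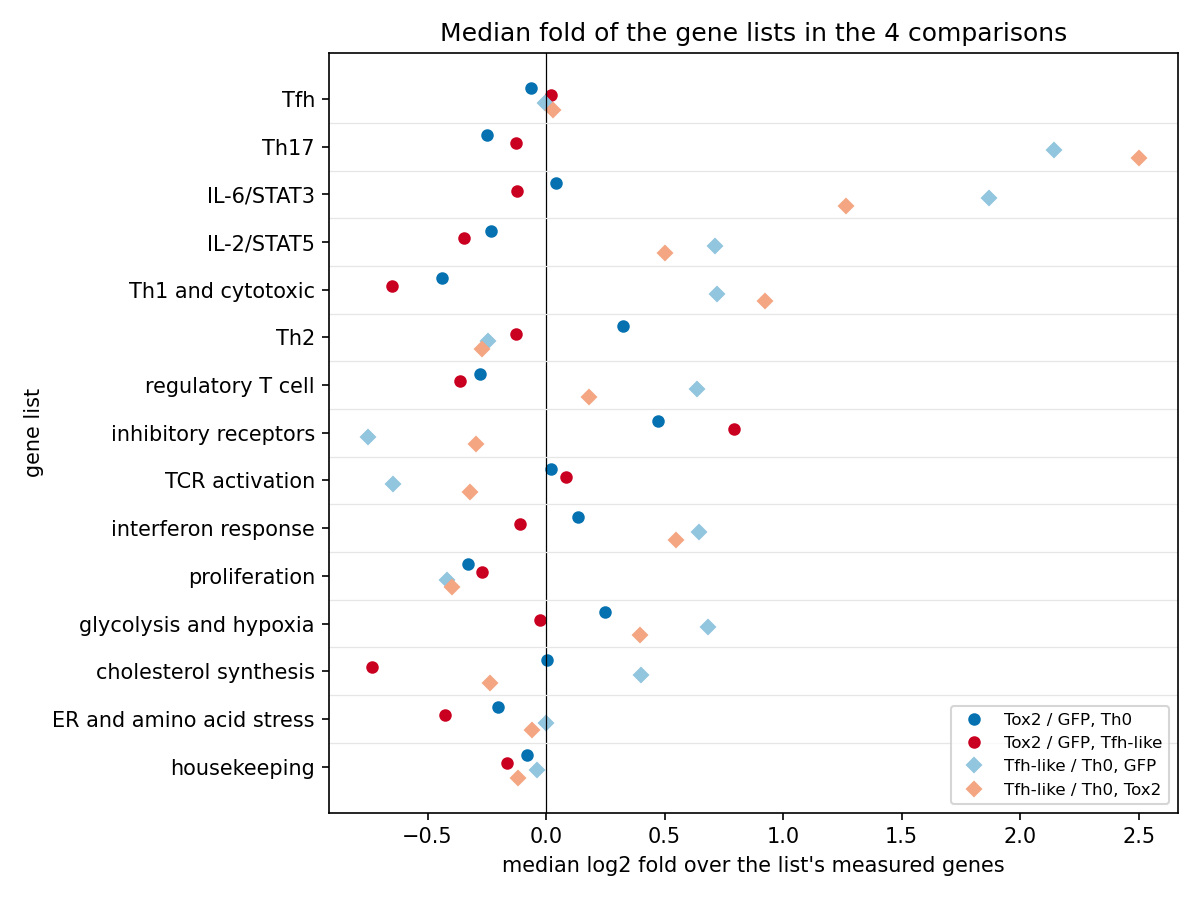
Median log2 fold over the measured genes of 15 of the lists (y axis), for Tox2 over GFP in each culture (circles) and Tfh-like over Th0 with each virus (diamonds); the spread of genes within a list is not drawn. Inhibitory receptors lie at 0.47 and 0.79 with Tox2 and at -0.75 and -0.30 with the culture, and Th1 and cytotoxic genes at -0.44 and -0.65 with Tox2 and at 0.72 and 0.92 with the culture.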

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

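For the carry-over explanations of Tox2 reads, the tests were chosen only after the result was seen. In 9 genes the Tox2 virus went with at least 2-fold higher expression in one culture and at least 2-fold lower expression in the other. Independent lists of the 519 and 521 genes 2-fold apart would give no fewer, so the number of these genes shows no effect of the culture. Each of the 9 rests on 1 library per group, and the difference itself was not tested. Tgm2, a transglutaminase, had a log2 fold of 2.57 in Th0 and -1.16 in Tfh-like, a difference of -3.73 (Tfh-like minus Th0). The hair keratin gene Krt83 had 1.43 and -2.13, a difference of -3.56. Cxcr6, a chemokine receptor, had -1.46 and 1.89, a difference of 3.34. Cnksr3 had -1.34 and 1.55, a difference of 2.89. The alarmin Il33 had 1.09 and -1.74, a difference of -2.84, from counts of 8 and 20 in Th0. Arhgap36 (-1.29 and 1.22), Enthd1 (1.18 and -1.22), C1s1 (-1.04 and 1.06) and Scd3 (1.04 and -1.03) had differences of 2.51, -2.40, 2.10 and -2.07.

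Tox2 was 6.01-fold higher in Tfh-like with GFP than in Th0 with GFP (851 against 144 counts), in cells that received no Tox2 virus. Carry-over of 2.41% of the reads of the Tox2 Th0 library would give as many Tox2 reads, but in 5 of 8087 genes with at least 5 predicted reads the upper exact Poisson limit of the count then lay below the prediction, among them Slc1a2 with 14 reads against 48.5 and H2-Eb2 with 0 against 17.8, which argues against that source. Carry-over of 2.64% from the Tox2 Tfh-like library left 0 of 8297 genes with that limit below the prediction (Slc1a2 had 14 reads against 18.8, with a limit of 23.5), so carry-over from that library cannot be told apart from Tox2 expressed by the cells, since both libraries share the culture. Higher endogenous Tox2 in the Tfh-like culture stays open as a hypothesis and was not tested.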

How the results depend on the processing

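The removal of GC and length trends was the alternative chosen after seeing the data. With DESeq2 484 genes passed for Tox2 (299 up, 185 down; 452 shared with edgeR's 746) and 1619 for the culture (1610 shared with edgeR's 2656). Scaling by total count gave 1193 for Tox2 (681 up, 512 down), which included all 746. With the other factor left out, edgeR called 0 genes for Tox2 (662 at an unadjusted p under 0.05) and 377 for the culture, since the other factor's effect then counts as spread. The correlation of the Tox2 folds was 0.617 at a CPM of at least 5; the cause was not tested. No total count of genes under the remaining alternatives moved by over 1.5 times, but counts by direction did: the genes with a higher Tox2 fold in Tfh-like went from 195 to 119 at a CPM of at least 5, and the genes lower with the culture from 1092 to 1827 with GC and length trends removed and to 1649 with total counts. No fold of a named gene that was 2-fold apart turned direction, nor did a list median that lay outside the random range, while medians inside it turned 19 times, counted over all settings. Of 692 folds of named genes, 12 fell short of the 2-fold rule and 5 newly met it with GC and length trends removed, and 21 fell short with a prior count of 10. Of 92 list medians, 83 kept their side of the random range with those trends removed, 88 at a CPM of at least 5 and 92 with total counts. At a CPM of at least 5, with fewer genes in the list, the Th2 median for the culture went from -0.24 to 0.46 with GFP and from -0.27 to 0.32 with Tox2. No replicate was left out, because the fit then has no residual degree of freedom. Beyond the additive model, which compares the viruses within each culture, no paired analysis was possible because each group has 1 library.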

Other observations

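For the directions of the Tox2 and culture folds, the tests of shared noise and of the genes opposite in both cultures were chosen only after the result was seen, and the removal of GC and length trends was chosen after seeing the data. In the amino acid and ER stress list 4 of 18 genes fell and 1 rose (10 adjusted over the list alone; medians -0.20 in Th0 and -0.43 in Tfh-like), with asparagine synthetase Asns at -1.39 (SE 0.15) and Trib3 at 1.02 (SE 0.18). Of 19 apoptosis genes 5 fell and 1 rose (9 adjusted over the list alone; medians -0.13 and -0.12): Bcl2l1 fell by -0.65, Bax by -0.61 and the near-identical pair Bcl2a1b and Bcl2a1d also fell, and Pmaip1 rose by 0.94 (SE 0.13). Of 21 migration genes 3 rose and 3 fell (8 adjusted over the list alone; medians -0.07 and -0.07), with the integrin Itga4 at 1.17 (SE 0.12). Of 15 naive and memory genes Tcf7 and Bach2 rose and Igfbp4 fell (4 adjusted over the list alone; medians 0.28 and -0.09). Of 10 genes that restrain the cell cycle Cdkn1b and Btg2 rose and Cdkn1a fell (7 adjusted over the list alone; medians 0.16 and 0.27). Among 23 chromatin regulators only the demethylase Kdm6b passed with edgeR (0.86, SE 0.12; 2 genes with DESeq2 or limma-voom; 3 adjusted over the list alone; medians 0.09 and -0.05), and among 23 oxidative phosphorylation genes only Cycs, which fell (0 with DESeq2; 1 adjusted over the list alone; medians -0.17 and -0.09). With GC and length trends removed the median in Th0 was -0.05 for oxidative phosphorylation (percentile 49.4) and -0.18 for amino acid and ER stress (percentile 4.11). Of 19 interferon response genes Zbp1 and Gbp2 fell (1 with DESeq2; 3 adjusted over the list alone; medians 0.13 and -0.11), and of 19 cholesterol synthesis genes Idi1 fell (2 adjusted over the list alone). Glycolysis and hypoxia genes had 0 of 24 passing with edgeR, DESeq2 or limma-voom (0 adjusted over the list alone; medians 0.25 and -0.02). In edgeR 6 of the 24 had an unadjusted p under 0.05, near the share over all genes of 3003 of 10960.

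With the culture, 11 of 21 migration genes rose and 5 fell (17 adjusted over the list alone; medians 0.41 with GFP and 0.68 with Tox2), with Cxcr4 at 1.66 (SE 0.12) and Gpr15 at 3.22 (SE 0.55). Of 15 naive and memory genes 6 rose and 5 fell (12 adjusted over the list alone; medians 0.20 and 0.05), Igfbp4 by 3.28 up and Dapl1 by -3.12 down. Of 13 regulatory T-cell genes 3 rose and 3 fell (9 adjusted over the list alone; medians 0.64 and 0.18), with Lrrc32 at 1.67 and Nrp1 at -1.25. Of 8 Th2 genes 3 rose and 4 fell (7 adjusted over the list alone; medians -0.24 and -0.27, which turned to 0.46 and 0.32 at a CPM of at least 5), with Nfil3 at 1.88 and Ccr8 at -1.58. Apoptosis genes (3 up and 5 down of 19, 10 adjusted over the list alone; medians -0.07 and 0.08) included Bcl2l11 at -1.59 (SE 0.13) and Fas at 1.27. Amino acid and ER stress genes (3 up and 4 down of 18, 7 adjusted over the list alone; medians -0.00 and -0.06) included Phgdh at -0.99. Chromatin regulators (3 up and 5 down of 23, 8 adjusted over the list alone; medians -0.13 and -0.23) included Dnmt3a at -0.85 and Hdac4 at 0.75. Cell-cycle restraint genes had 3 up and 2 down of 10 (6 adjusted over the list alone; medians -0.25, or -0.21 with a percentile of 10.8 with GC and length trends removed, and -0.02), with Cdkn1a at 1.25. Oxidative phosphorylation had only Ndufa4 of 23 passing (1 adjusted over the list alone; medians -0.08 and -0.01), and cholesterol synthesis Idi1 and Dhcr7 of 19, both down (1 adjusted over the list alone; medians 0.40 and -0.23).

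Markers of CD4+ T cells were high in each library, with Cd4 between 14423 and 24305 counts; Cd4 rose with Tox2 by 0.49 and Cd5 fell by -0.65 (2 of 10 adjusted over the list alone), and Cd2 and Cd28 rose with the culture by 1.43 and 0.54. Of the markers of other cell types, those measured were 4 of 15 for B cells, 1 of 2 for CD8+ T cells, 1 of 10 for NK and gamma-delta T cells, 4 of 14 for myeloid cells, 3 of 8 for dendritic cells, 3 of 8 for stromal cells and 0 of 8 for erythroid cells, of which Hba-a1 was in the files with 10 counts or fewer and missed the CPM minimum. Activated T cells also express several of these. With Tox2 in Tfh-like all 4 myeloid and all 3 dendritic markers had log2 folds above 0 (medians 0.71 and 0.77, with Itgam and Xcr1 2-fold higher), against medians of -0.08 and 0.19 in Th0; 0 of them passed for Tox2 with edgeR, DESeq2 or limma-voom (2 myeloid and 0 dendritic at an unadjusted p under 0.05). Cd74 fell with Tox2 (-0.87) and with the culture (-2.04), while H2-Ab1 and Ebf1 rose with the culture by 1.60 and 2.72. Klrd1, Batf3, Col1a1 and Krt18 rose and Pecam1 fell with the culture, with at most 54, 44, 176 and 60 counts for the first 4. Of the family list, Tox2 rose with the virus and Tox fell with the culture, out of 3 measured genes. Gm10800, a predicted gene chosen after its values were seen, had 5391 counts in Th0 with GFP and 21, 9 and 11 in the other libraries; whether these reads belong to it was not resolved.

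Of the genes 2-fold apart in both pairs, 31 were higher with Tox2 and lower with the Tfh-like culture (Ccr8, Eomes, Il9r and Wnt10b among them, where independent lists would share 2.09) and 20 were lower with Tox2 and higher with the culture (Il17f, Spp1 and Timp1, 3.11 for independent lists), against 11 and 5 in the same direction (6.76 and 0.962). Opposite directions made up 76.1% of these overlaps, which could come from noise of the shared libraries. In single pairs the share was 76.1% and 79.7% where the shared library pushes to opposite directions. Where it pushes to the same direction, the share was 41.3% (Tox2 in Th0 against the culture with GFP) and 58.3% (Tox2 in Tfh-like against the culture with Tox2). These shares alone leave open whether opposite directions prevail. Among the 1024 genes 2-fold apart by the mean of both culture folds, 64 were opposite to the culture with Tox2 in both cultures. Another 24 went along the culture in both, and 3 had Tox2 folds in opposite directions, of which 2 went against the culture in Tfh-like only. The mean culture fold weighs both libraries of a Tox2 pair equally, so their noise favours neither direction if libraries vary alike. By this measure more genes were opposite than along the culture, with genes not independent and 1 library per group. Noise of single libraries would give fewer than 3 for the 64, and a weaker response of the Tox2 Tfh-like library as many of the 64 as of the 2. Neither was seen, but this cannot decide about opposition to the culture. The Tox2 folds agreed between the cultures whatever their relation to the culture, and the 24 also outnumber the 3. How far a weaker response of the whole Tox2 Tfh-like library adds to the folds in Tfh-like stays open. The planned bound was met. The median Tox2 fold in Tfh-like was -0.70 (SD 1.01) over 104 genes at least 8-fold higher with the culture in GFP. For the genes lower with Tox2 and higher with the culture it was -1.89. The bound was wrongly set, since the latter genes were chosen for a Tox2 fold at least 2-fold lower. The 104 genes were chosen on the Tfh-like library with GFP, whose noise pushes their Tox2 fold in Tfh-like below 0. Of the 104, 36 were 2-fold lower and 3 were 2-fold higher with Tox2 in Tfh-like, which that noise could give in part. Over all 10960 genes the mean Tox2 and culture folds had a Pearson r of -0.129 and a Spearman rho of 0.0399, and a Tox2 effect against the response to IL-6 in these genes remains an untested hypothesis.

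The Tox2 folds of the 2 cultures, which share no library, had a correlation across genes of 0.580. Transduction and sorting came before culture, so both pairs may share that step and need not be independent of it, which was not tested. A GC content or length trend common to both comparisons could give such a correlation, but it was 0.587 after the trends were removed, which argues against that source as the whole cause. A Tox2 effect common to both cultures stays open as a hypothesis, with no replicate library to test it.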
